A study of Homo sapiens with 10 samples.

How the data were processed

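RNA sequencing was done on 10 libraries of lines derived from U2OS, a human osteosarcoma cell line. A control CRISPR line is labelled p53 wild type and a second line p53 knockout. Each line received a control siRNA or an siRNA against SET, a histone chaperone and inhibitor of protein phosphatase 2A that binds p53, for 96 h per the labels' protocols. The groups were cells labelled p53 WT with control siRNA (n = 3) or SET siRNA (n = 3) and cells labelled p53 KO with control siRNA (n = 2) or SET siRNA (n = 2). The labels call the libraries biological replicates without saying how the cultures were separated, so p-values measure the spread between these libraries. The series design text contradicts itself, since it names SET as the target of the CRISPR construct while describing a p53 knockout line. Groups were taken from the sample labels.

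Total RNA was extracted with Trizol and made into TruSeq libraries per the labels' protocols. Reads were processed with bcl2fastq 1.8.4, TopHat2 2.0.4 and Cufflinks 2.0.2 per the submitters' processing notes. The deposited files hold FPKM per gene, computed by the authors with Cufflinks, with a confidence interval and a status per gene per the file headers. Genome build and annotation are not given in the sources used here. Coordinates are printed as the files give them, counted from 1. Each file held 25593 entries with 25548 distinct symbols, and 45 entries repeated a symbol already listed. Between 3 and 12 genes per library had a failed status, and 78 had too little data. No mitochondrially encoded gene was listed, so that list could not be measured.

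Depth was not stated. The authors' FPKM intervals imply 14288902 to 21775347 fragments per library, although 61.9 to 62.7% of the implied fragment numbers of low genes were whole within 0.05, so these are estimates and no count test was used as the principal test. The median half-width of the authors' intervals was 7.44 to 9.21% of FPKM.

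Genes with FPKM of at least 1 in at least 2 libraries were tested, which left 14813 tested and 10780 not tested. Values were log2(FPKM + 1). Fold changes on this scale understate changes of low genes, and an interaction on it can differ from the ratio of FPKM folds. limma 3.58.1 in R 4.3.3 fitted all 10 libraries with 4 groups (lmFit, contrasts.fit and eBayes with trend), and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Every adjusted p of a gene is from limma. The 5 contrasts were SET siRNA against control siRNA in each line, their difference (the interaction), and KO against WT under each siRNA. Gene lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. List p-values were adjusted by Benjamini-Hochberg within a contrast. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

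The procedure was tested on simulated data with 200 of 14813 genes changed. For the siRNA comparison in WT-labelled cells 91% of 1.5-fold and 99% of 2-fold changes were recovered, with 3.6% of calls false. For KO-labelled cells these were 84%, 99% and 6.2%, and for KO against WT with control siRNA 88%, 100% and 6.5%. These rates describe only the genes changed in the simulation and were not measured for low genes. Nor were they measured for the larger spread between the KO-labelled libraries with control siRNA. They are therefore not rates for every tested gene, and may be too favourable in those cases.

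Named genes were chosen by rule: the 8 largest rises and 8 largest falls among called genes whose groups did not overlap (called alone for the interaction), SET, CDKN1A, MDM2 and BBC3 always, and the 2 to 4 called members of each described list with the largest change. Some results that this rule selects are not reported here. GAPDH was named after its values were seen. Small RNA symbols were left out, but RN5S4 and RN5S5 did not match the excluded prefixes. The lists were p53 targets in 3 parts (arrest and feedback, apoptosis, and repair, metabolism and other) and their union, G2/M cell cycle, G1/S and DNA replication, SET partners and p53 acetylation, interferon response, NF-kB and inflammatory, ATF4 amino acid response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia and glycolysis, extracellular matrix, ferroptosis and iron, immediate early, cytosolic ribosomal proteins, replication-dependent histones, and epithelial, blood and endothelial markers.

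Regional differences were measured as medians of log2 change in 664 windows of 30 neighbouring genes. The windows covered 10468 genes with mean FPKM of at least 5 and were set against 1000 shuffles of gene order. Adjacent windows overlapped and shared genes, so windows are not independent of each other. Alternatives were another pseudocount, no or a stricter filter, median-of-ratios and quantile scaling, a fit on only the libraries compared, a replicate block, no trend, array weights, genes of clean status, a 2-fold minimum, each library left out, voom on implied fragments, and shared controls split between comparisons. Planned count tests were not run because the files hold FPKM.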

Results

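The data were FPKM values from 10 libraries of a U2OS-derived control line labelled p53 WT and a line labelled p53 KO, each given control or SET siRNA. Between 13804 and 14153 genes reached FPKM 1 per library. Implied depth was 14288902 to 21775347 fragments, with the second SET siRNA library of the KO-labelled line the deepest. Against counting noise the KO control pair had a chi-square per degree of freedom over implied fragments of 3.697, and the other pairs within a group 1.435 to 2.089. On the log2 scale that pair correlated across genes at 0.991, within the 0.989 to 0.992 of all such pairs, where genes are not independent replicates. The series title places the question in the genes governed by the interplay of p53 and SET.

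SET mRNA was 124 ± 2.64 FPKM (SD, n = 3) in WT-labelled cells with control siRNA and 12.5 ± 0.656 (n = 3) with SET siRNA. In KO-labelled cells it was 164 ± 8.22 (n = 2) and 14.9 ± 0.0302 (n = 2). SET (chromosome 9, 131445934 to 131458675) fell by 3.21 on the log2 scale in WT-labelled cells (adjusted p = 1.26e-09) and had a log2 change of -3.37 in KO-labelled cells (adjusted p = 5.14e-09). A gene-level FPKM does not test a CRISPR edit, so the lines are called WT-labelled and KO-labelled throughout.

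**Figure D1:**
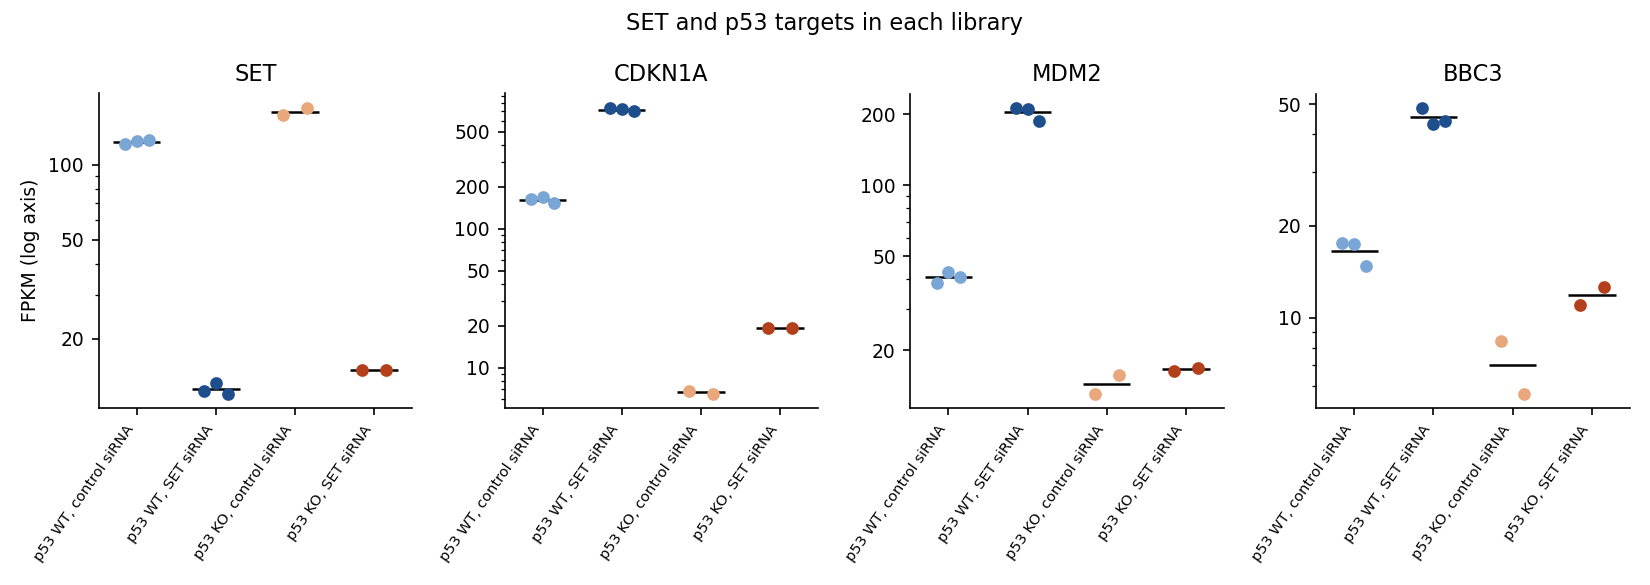
FPKM on log axes of SET, CDKN1A, MDM2 and BBC3 in each library (points), with group means as bars. SET lay between 12.01 and 14.93 in the 5 SET siRNA libraries and between 120.9 and 169.7 in the 5 control siRNA libraries.

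The comparison of SET siRNA with control siRNA in WT-labelled cells asked which genes respond to the siRNA where p53 is labelled intact. The sequence and number of siRNAs are not given in the sources used here, and off-target effects were not assessed. GDF15, a stress-induced cytokine, went from 18.5 ± 2.14 to 193 ± 9.16 FPKM, 10.5-fold (n = 3 and 3). MDM2, the ubiquitin ligase that restrains p53, went from 40.9 ± 2.09 to 204 ± 14.3 FPKM, and CDKN1A, the cell cycle inhibitor p21, from 162 ± 8.42 to 720.3 ± 21.2. ATF3, a stress transcription factor, rose 5.59-fold and NOS3, endothelial nitric oxide synthase, 11.9-fold. Tropomyosin TPM4 fell from 113 ± 1.11 to 29.7 ± 2.1 FPKM and cardiac troponin TNNT2 from 8.33 ± 0.757 to 1.13 ± 0.145. In limma 8117 of 14813 genes were called, 4564 higher and 3553 lower, and 345 changed at least 2-fold (188 higher, 157 lower). The higher share of calls was 56.2%, and 50.1% after median-of-ratios scaling.

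The other large rises in WT-labelled cells were LOC100653010, LINC00326, HTN1 and NBEAP1, by 3.26, 3.00, 2.53 and 2.42 on the log2 scale. LOC100653010 (chromosome 19, 18499397 to 18516317) overlaps GDF15 (18496968 to 18499986), and the 2 cannot be separated without strand. LBH, SETP20, FOXS1 and MFAP5 fell by 1.95, 1.92, 1.84 and 1.84. SETP20 is a near-identical copy of SET and its value is uncertain. The ribosomal RNA gene RN5S4 had a log2 change of -2.51 (adjusted p = 0.0168), and its call was lost without WT control library 1 (adjusted p = 0.0577), SET siRNA library 2 (0.0614) or 3 (0.0606), and under voom (0.822).

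Among p53 targets of arrest and feedback, 14 of 15 rose and 1 fell (14 and 1 adjusted over the list alone), with CDKN1A at 2.15, MDM2 at 2.29 and the antioxidant regulator SESN2 at 1.77 on the log2 scale. Of apoptosis targets 14 of 16 rose (14 adjusted over the list alone), including BBC3, which encodes PUMA, at 1.40 and the death receptors FAS at 1.33 and TNFRSF10B at 1.16. Of repair, metabolism and other targets 25 of 29 rose and 1 fell (25 and 1 adjusted over the list alone), with INPP5D at 1.64 and the ceramidase ACER2 at 1.43. Camera gave adjusted p = 5.33e-08, 5.23e-06 and 2.43e-09. The last was lost, with adjusted p = 0.0623 with an estimated correlation. Over the 60 measured targets together 53 rose and 2 fell (53 and 2 adjusted over the list alone; p = 3.95e-17, and 0.00525 with an estimated correlation). In WT-labelled cells the arrest, apoptosis, G1/S, ATF4 and joint p53 lists kept their calls with an estimated correlation.

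Proliferation genes were lower in WT-labelled cells. Of G2/M genes 28 of 30 fell and 0 rose (28 and 0 adjusted over the list alone), among them cyclin CCNA2 at -1.62, the kinase PLK1 at -1.09 and CDC20, an activator of the anaphase-promoting complex, at -1.07. Of G1/S and replication genes 34 of 39 fell and 1 rose (34 and 1 adjusted over the list alone), with CCNE2 at -1.07 and GINS1 at -0.96. Camera gave adjusted p = 6.02e-13 and 4.69e-12. The G2/M call was lost, with adjusted p = 0.0879 with an estimated correlation.

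ATF4 amino acid response genes rose in 20 of 23 cases (21 adjusted over the list alone), with NUPR1 at 1.71, DDIT3 at 1.64 and CHAC1 at 1.59 (camera adjusted p = 1.13e-09). Of NF-kB and inflammatory genes 13 of 17 rose and 3 fell (13 and 3 adjusted over the list alone), with CSF2 at 2.02 and the protease MMP3 at 1.99 (adjusted p = 0.00752, and adjusted p = 0.169 with an estimated correlation). Of matrix genes 14 of 24 fell and 3 rose (14 and 4 adjusted over the list alone), with COL3A1 at -1.64 and SPARC at -1.45, while TGFBI rose by 1.25 (adjusted p = 0.0025, and adjusted p = 0.382 with an estimated correlation). Of interferon genes 12 of 22 fell and 5 rose (12 and 5 adjusted over the list alone), with IFIT1 at -1.14 and IFI6 at -1.07 against ISG20 at 0.94 (adjusted p = 0.0102, and adjusted p = 0.169 with an estimated correlation).

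SET partners, which include the phosphatase subunit PPP2CA and the chaperone NAP1L4, fell in 14 of 27 cases and rose in 3 (14 and 3 adjusted over the list alone; adjusted p = 0.00855, and adjusted p = 0.11 with an estimated correlation). PPP2CA went from 54.9 ± 2.3 to 28.1 ± 1.08 FPKM and NAP1L4 changed by -0.58. Of chaperone genes 8 of 15 rose (8 adjusted over the list alone), with DNAJC3 at 0.96 and HERPUD1 at 0.77 (adjusted p = 0.0461, and adjusted p = 0.619 with an estimated correlation). Cholesterol genes had 2 rises and 6 falls among 23 (2 and 6 adjusted over the list alone), with HSD17B7 at 0.53 and ACAT2 at -0.53, and the list was not called (adjusted p = 0.164).

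In KO-labelled cells the same siRNA comparison asked which of these responses are seen where p53 is labelled absent. CDKN1A was 6.67 ± 0.231 FPKM with control and 19.4 ± 0.111 with SET siRNA (n = 2 and 2), 2.9-fold, and GDF15 rose 3.29-fold from 4.79 ± 0.823. MDM2 was 14.4 ± 1.86 and 16.6 ± 0.298 FPKM and was not called (adjusted p = 0.118), although it was called without KO control library 2 (0.32, adjusted p = 0.0272). UCA1, a long noncoding RNA, rose from 3.18 ± 0.369 to 21.7 ± 1 FPKM. KRT17, a keratin, fell from 87.1 ± 13.2 to 18.4 ± 2.42 and COL3A1, a fibrillar collagen, from 15 ± 1.85 to 1.59 ± 0.571. In limma 5571 genes were called, 2926 higher and 2645 lower, with 247 at least 2-fold (102 higher, 145 lower). After median-of-ratios scaling the majority turned, with 2680 higher and 2859 lower. It also turned in a fit on only the libraries compared, which called 3202 genes, 1595 higher and 1607 lower. Without SET siRNA library 1 or 2 of these cells the count was 3463 or 3696, where the lone library is assumed to vary like the other groups.

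Other large rises in KO-labelled cells were HTN1, LINC00326, LINC00161, ATP6V0D2, HTN3 and NOS3, by 1.94 to 2.84 on the log2 scale. KRTAP21-2 rose by 1.98 but was listed at 0 in both control libraries. SETP20, EDN2, LOC645638 and TPM4 fell by 2.38, 2.32, 1.92 and 1.92. RN5S5 had a log2 change of -3.82 (adjusted p = 0.0183), lost without KO control library 2 (adjusted p = 0.11), SET siRNA library 1 (0.0756) or 2 (0.072), under array weights (0.0517) and under voom (0.797).

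Among the 60 p53 targets 14 rose and 14 fell in KO-labelled cells (14 and 15 adjusted over the list alone). The joint list, tested alone in each comparison, was not called (camera adjusted p = 0.859). The median was -0.03 and the mean 0.07, while camera pointed down. Arrest targets had 5 rises and 5 falls among 15 (5 and 6 adjusted over the list alone; adjusted p = 0.766), with CDKN1A at 1.41, GDF15 at 1.54 and SESN2 at 1.08. Apoptosis targets had 5 rises and 4 falls among 16 (5 and 4 adjusted over the list alone; adjusted p = 0.773), with AEN at 0.91, BBC3 at 0.70 and APAF1, the apoptosome scaffold, at -0.83. The remaining targets had 4 rises and 5 falls among 29 (4 and 5 adjusted over the list alone; adjusted p = 0.488), with TGFA at 1.16 and RAP2B at -0.55. Medians of the first 2 lists were -0.06 and 0.00 with means of 0.19 and 0.06 and camera pointing up, and the third had a median of -0.05 and a mean of 0.01 with camera pointing down.

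ATF4 genes rose in 15 of 23 cases and fell in 1 (16 and 1 adjusted over the list alone) in KO-labelled cells, with ATF3 at 1.40, DDIT3 at 1.26 and NUPR1 at 1.23 (adjusted p = 7.49e-06, and 0.0262 with an estimated correlation, the single list call there that held). G1/S genes rose in 18 of 39 cases and fell in 2 (19 and 2 adjusted over the list alone), with CCNE1 at 0.55 and E2F2 at 0.52 (adjusted p = 0.00175, and adjusted p = 0.405 with an estimated correlation). G2/M genes had 3 rises and 7 falls among 30 (2 and 2 adjusted over the list alone; adjusted p = 0.206), with UBE2C at 0.34 and CCNA2 at -1.08. NF-kB genes rose in 13 of 17 cases and fell in 1 (13 and 1 adjusted over the list alone), with CXCL3 at 1.49 and MMP1 at 1.44 (adjusted p = 0.000106, and adjusted p = 0.12 with an estimated correlation). Interferon genes fell in 13 of 22 cases and rose in 1 (14 and 1 adjusted over the list alone), with IFI6 at -0.92 against ISG20 at 1.02 (adjusted p = 0.000147, and adjusted p = 0.12 with an estimated correlation).

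Cholesterol genes rose in 11 of 23 cases and fell in 1 in KO-labelled cells (11 and 1 adjusted over the list alone), with MVK, mevalonate kinase, at 0.64 (adjusted p = 0.00666, and adjusted p = 0.205 with an estimated correlation). Matrix genes fell in 12 of 24 cases and rose in 4 (13 and 4 adjusted over the list alone), with SPARC at -1.44 and TGFBI at 1.61 (adjusted p = 0.00299, and adjusted p = 0.435 with an estimated correlation). SET partners had 2 rises and 6 falls among 27 (2 and 6 adjusted over the list alone; adjusted p = 0.227), with PPP2CA at -1.05 and the acetyltransferase KAT2B at -0.73. Chaperones had 1 rise and 3 falls among 15 (1 and 3 adjusted over the list alone; adjusted p = 0.488).

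The interaction asked whether the response to SET siRNA differed between the lines, as the WT-labelled response minus the KO-labelled response. MDM2 rose 5-fold in WT-labelled cells and was at 1.15-fold in KO-labelled cells, an interaction of 2.10 on the log2 scale (adjusted p = 4.9e-05). SESN1, TP53INP1 and BTG2, all p53 targets, had interactions of 1.86, 1.87 and 1.83, and FAS 1.74. CDKN1A rose in both lines with an interaction of 0.74 (adjusted p = 0.000469). CDC20 and PLK1 had interactions of -1.04 and -1.01, since they fell in WT-labelled cells while KO-labelled means were 147 and 143 and 83.1 and 78.3 FPKM. In limma 2831 genes were called, 1557 positive and 1274 negative, and 92 reached 1 in size (64 and 28). After quantile normalization 1333 were positive and 1339 negative. SET did not differ (0.16, adjusted p = 0.146).

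The interaction count depended on single libraries. It was 1820 and 1760 without WT SET siRNA library 1 or 2, 4589 and 1724 without KO control library 1 or 2, and 1143 and 1466 without KO SET siRNA library 1 or 2. BBC3 had an interaction of 0.70 (adjusted p = 0.0358), lost when any library was left out except the KO control libraries, with adjusted p from 0.0528 to 0.135, and with a pseudocount of 0.1 (0.055), no filter (0.0654) or voom (0.0532).

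**Figure D2:**
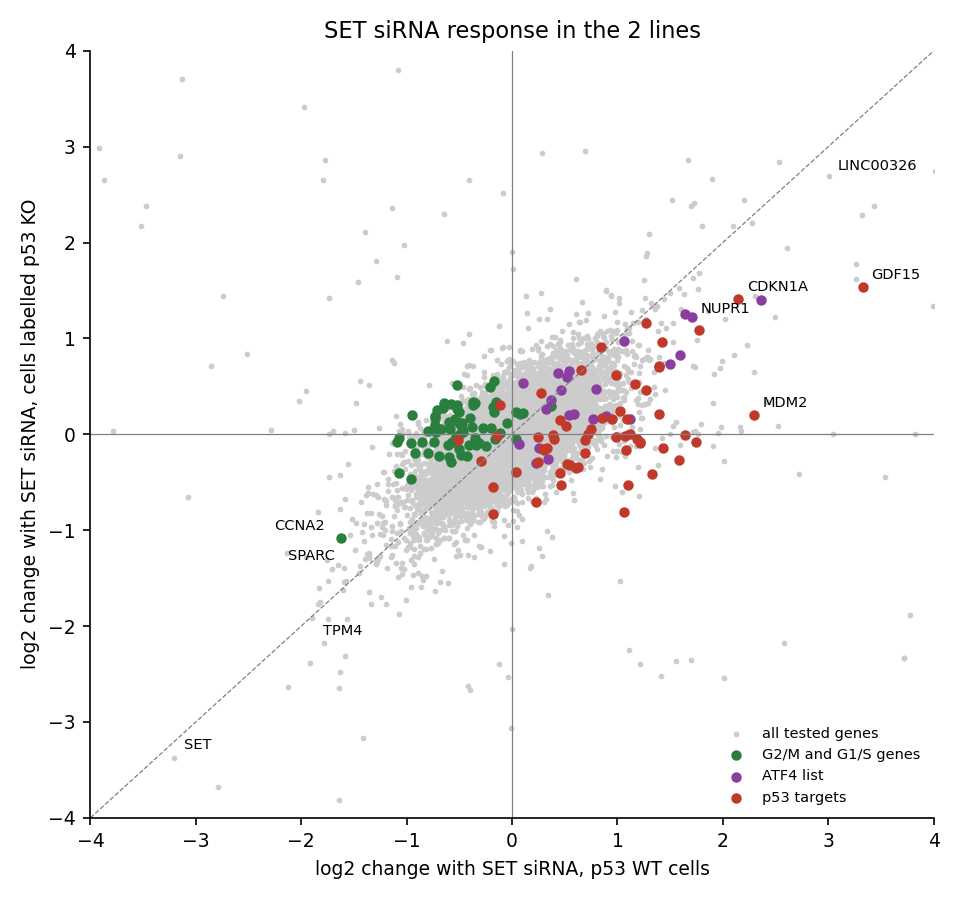
Log2 change with SET siRNA in WT-labelled cells (x axis) against KO-labelled cells (y axis) for 14813 tested genes (grey; 18 lie outside the axes), with p53 targets in red, G2/M and G1/S genes in green, ATF4 list genes in purple and equal responses on the dashed line. Across genes, which are not independent replicates, Pearson's r was 0.465.

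Positive interactions by size were MDM2, NBEAP1 at 2.08, CCL3 at 2.03, PVRL4 at 1.94, C8orf75 at 1.90, TP53INP1, SESN1 and SCHIP1 at 1.84. SCHIP1 (adjusted p = 0.0492) lost its call in 8 of the 10 left-out libraries, namely WT control libraries 1 and 3, WT SET siRNA libraries 1 and 2 and all 4 KO libraries, with adjusted p from 0.053 to 0.147. Its call was also lost with a pseudocount of 0.1 (0.0698), no filter (0.0899), median-of-ratios (0.0504) or quantile scaling (0.0579), no trend (0.0564) and array weights (0.118). Negative interactions were LOC100652895 at -3.10, KRTAP21-2 at -3.00, LOC100652795 at -2.73, HIST1H4I at -1.99, KRTAP20-2 at -1.90, LOC100505817 at -1.54, SPRR2D at -1.31 and ANXA10 at -1.29. LOC100652795 lost its call without KO control library 2 (adjusted p = 0.0671) or KO SET siRNA library 1 (0.0749), and HIST1H4I with a pseudocount of 0.1 (0.0549). C8orf75, KRTAP20-2 and LOC100505817 lost theirs under voom (0.167, 0.226 and 0.131). KRTAP20-2 was listed at 0 in every library but the KO SET siRNA pair, at 2.74 ± 0.517 FPKM.

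Of the 60 p53 targets 51 had a positive and 1 a negative interaction (52 and 1 adjusted over the list alone; camera p = 9.37e-27, and 0.0016 with an estimated correlation). By part these were 14 and 1 of 15 for arrest (14 and 1 adjusted over the list alone), 12 and 0 of 16 for apoptosis (13 and 0) and 25 and 0 of 29 for the rest (25 and 0), with TP53I3 at 1.63, INPP5D at 1.65 and ACER2 at 1.57. Camera gave adjusted p = 7.94e-13, 8.97e-08 and 2.32e-15. G2/M genes were negative in 22 of 30 cases (25 adjusted over the list alone; adjusted p = 9.65e-17) and G1/S genes in 32 of 39 (33 adjusted over the list alone; adjusted p = 1e-23), with UHRF1 at -1.16 and E2F2 at -1.04. With an estimated correlation the 3 p53 lists, both cycle lists, ATF4 and cholesterol held.

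ATF4 genes were positive in 13 of 23 cases and negative in 1 (14 and 2 adjusted over the list alone; adjusted p = 0.000102), with ATF3 at 0.97 and CTH at 0.96. Cholesterol genes were negative in 12 of 23 cases (12 adjusted over the list alone; adjusted p = 7.47e-06), with DHCR7 at -0.70. Chaperones were positive in 6 of 15 cases (11 adjusted over the list alone; adjusted p = 0.000336, and adjusted p = 0.519 with an estimated correlation). DNAJC3 at 0.70 lost its call without KO control library 2 (0.0669) or KO SET siRNA library 1 (0.0619) or 2 (0.0631). DNAJB9 at 0.67 lost its call without WT control library 1 (0.0513), WT SET siRNA library 1 (0.0509) or 2 (0.0525), KO control library 2 (0.0768) or KO SET siRNA library 2 (0.0843). Matrix genes had 4 positive and 2 negative interactions among 24 (5 and 2 adjusted over the list alone; adjusted p = 0.441), a median of -0.07 and a mean of 0.01 with camera pointing down.

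**Figure D3:**
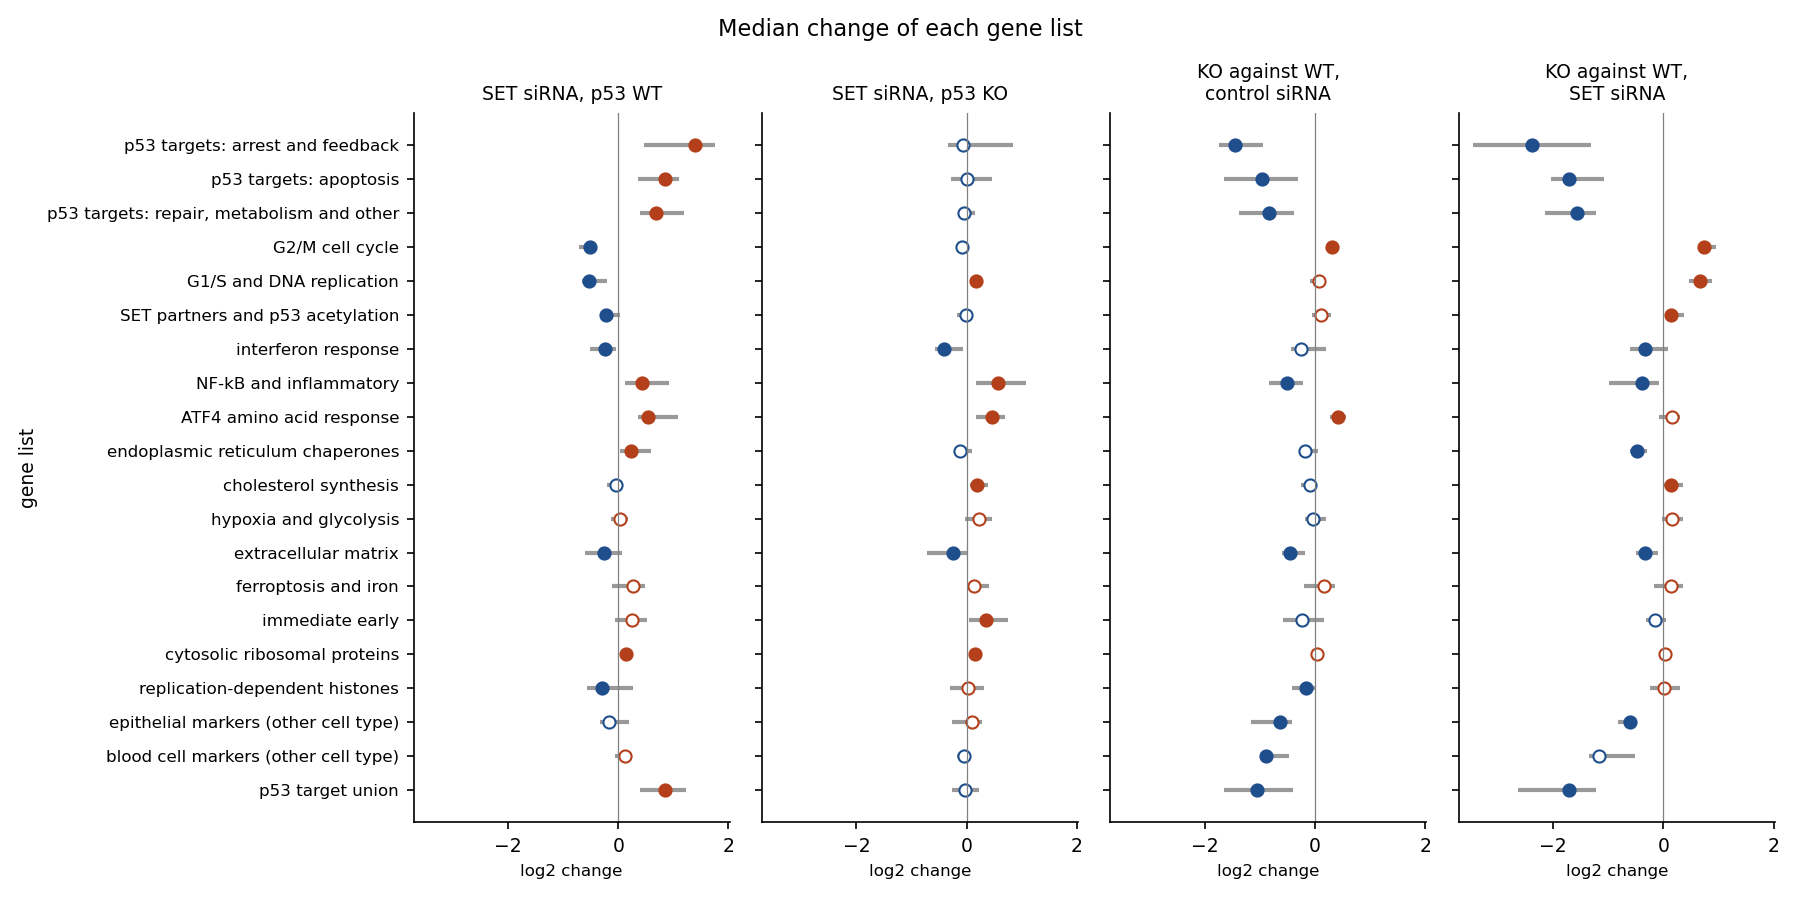
Median log2 change of each gene list with SET siRNA in each line and between the lines under each siRNA, with grey bars for the interquartile range of members and medians above 0 in red and below 0 in blue. Filled points had a camera adjusted p below 0.05, as for G1/S genes in WT-labelled cells with a median of -0.52, before any estimated correlation.

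The comparison of KO-labelled with WT-labelled cells under control siRNA asked which genes differ between the lines without SET siRNA. CDKN1A was 6.67 ± 0.231 FPKM in KO-labelled (n = 2) and 162 ± 8.42 in WT-labelled cells (n = 3), a log2 difference of -4.41 (adjusted p = 1.68e-10). The p53 targets DDB2, which acts in nucleotide excision repair, and TRIM22 were lower by -2.74 and -3.09. KISS1 was at 7.69 ± 0.483 against 133 ± 14.2 FPKM and UCA1 at 3.18 ± 0.369 against 64.4 ± 8.03. GLUL, glutamine synthetase, was higher at 6.35 ± 0.123 against 0.311 ± 0.0739 FPKM. In limma 7101 genes were called, 3810 higher and 3291 lower in KO-labelled cells, with 373 at least 2-fold (94 higher, 279 lower). After median-of-ratios scaling the majority turned, with 3412 higher and 3579 lower. The design text describes 1 line per genotype, so differences of p53 status and of line cannot be separated by this design.

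Other large differences under control siRNA were LOC643714 at 4.74 (listed at 0 in WT-labelled cells), MT1G at 2.65, FGF21 at 2.10, BCR at 2.06, CDRT4 at 2.01, LOC100652751 at 2.00 and COL3A1 at 1.97, and MYH16 at -3.96, LOC100507165 at -3.68 (listed at 0 in KO-labelled cells) and CTAG2 at -3.60. Of the 60 p53 targets 52 were lower and 0 higher (52 and 0 adjusted over the list alone; p = 3.37e-28, and 0.00139 with an estimated correlation). By part 14 of 15, 12 of 16 and 26 of 29 were lower (14, 12 and 26 adjusted over the list alone), with MDM2 at -1.45, BTG2 at -2.05, FDXR at -2.52, CYFIP2 at -2.02, EDA2R at -1.91 and BBC3 at -1.15 (camera adjusted p = 1.06e-12, 4.42e-08 and 5.65e-16). ATF4 genes were higher in 17 of 23 cases and lower in 2 (17 and 2 adjusted over the list alone), with CTH at 1.28 and TRIB3 at 0.92 (adjusted p = 5.52e-06). The p53 and ATF4 list calls held with an estimated correlation.

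G2/M genes were higher in 26 of 30 cases and lower in 1 in KO-labelled cells under control siRNA (26 and 1 adjusted over the list alone), with KIF11 at 0.93, AURKB at 0.92 and TTK at 0.64 (adjusted p = 1.73e-06, and adjusted p = 0.234 with an estimated correlation). NF-kB genes were lower in 11 of 17 cases and higher in 1 (11 and 1 adjusted over the list alone), with CSF2 at -1.91 and BIRC3 at -1.56 (adjusted p = 5.9e-06, and adjusted p = 0.0509 with an estimated correlation). Matrix genes were lower in 18 of 24 cases and higher in 3 (18 and 3 adjusted over the list alone), with CTGF at -1.07 (adjusted p = 2.01e-05, and adjusted p = 0.234 with an estimated correlation). Epithelial markers were lower in 5 of 6 cases (5 adjusted over the list alone), with KRT8 at -1.50 and KRT14 at -1.29 (adjusted p = 0.000608, and adjusted p = 0.149 with an estimated correlation). Blood cell markers were lower in 2 of 3 cases (2 adjusted over the list alone), LCP1 at -1.13 and LAPTM5 at -0.89 (adjusted p = 0.0306, and adjusted p = 0.202 with an estimated correlation). Interferon genes had 5 higher and 10 lower members (5 and 10 adjusted over the list alone; adjusted p = 0.17), with IFI44 at -1.68, OAS3 at -1.12 and IFIT1 at 1.09. Histone genes were lower in 12 of 35 cases (8 adjusted over the list alone; adjusted p = 0.0194, and adjusted p = 0.335 with an estimated correlation).

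Some of the line differences lay in blocks along chromosomes. Of 664 overlapping windows 62 lay beyond the shuffled range with control siRNA and 50 with SET siRNA. Shared windows numbered 38 (14 higher, 24 lower) on 6 chromosomes. For the siRNA comparisons 1 and 4 windows lay beyond the shuffled range. The block on chromosome 17 from 7476024 to 21218552, with window medians of 0.56 to 0.89 with control siRNA and 0.46 to 0.89 with SET siRNA, holds AURKB and RPL26 (1326 ± 22.5 against 583 ± 30 FPKM). Lower blocks lay on chromosome 16 from 54952775 to 80838175, which holds HERPUD1, on chromosome 7 from 91875548 to 102740205, which holds MYH16, and on chromosome 12 from 87984 to 7261869. RPL13 lay in a separate lower window of chromosome 16, from 87636499 to 89987385. GAPDH, in the block on chromosome 12, was at 1602 ± 187 against 3090 ± 124 FPKM. KIF11, IFIT1, FAS and LOC100652751 lay in higher windows of chromosome 10 and FDXR in a lower window of chromosome 17. Of the 60 p53 targets 6 lay inside shared windows. These windows held 750 genes, 7.2% of those placed. With control siRNA they held 623 of 7101 calls and 53 of 373 called at least 2-fold. With SET siRNA they held 581 of 7173 and 54 of 527, so most called line differences lay outside them.

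**Figure D4:**
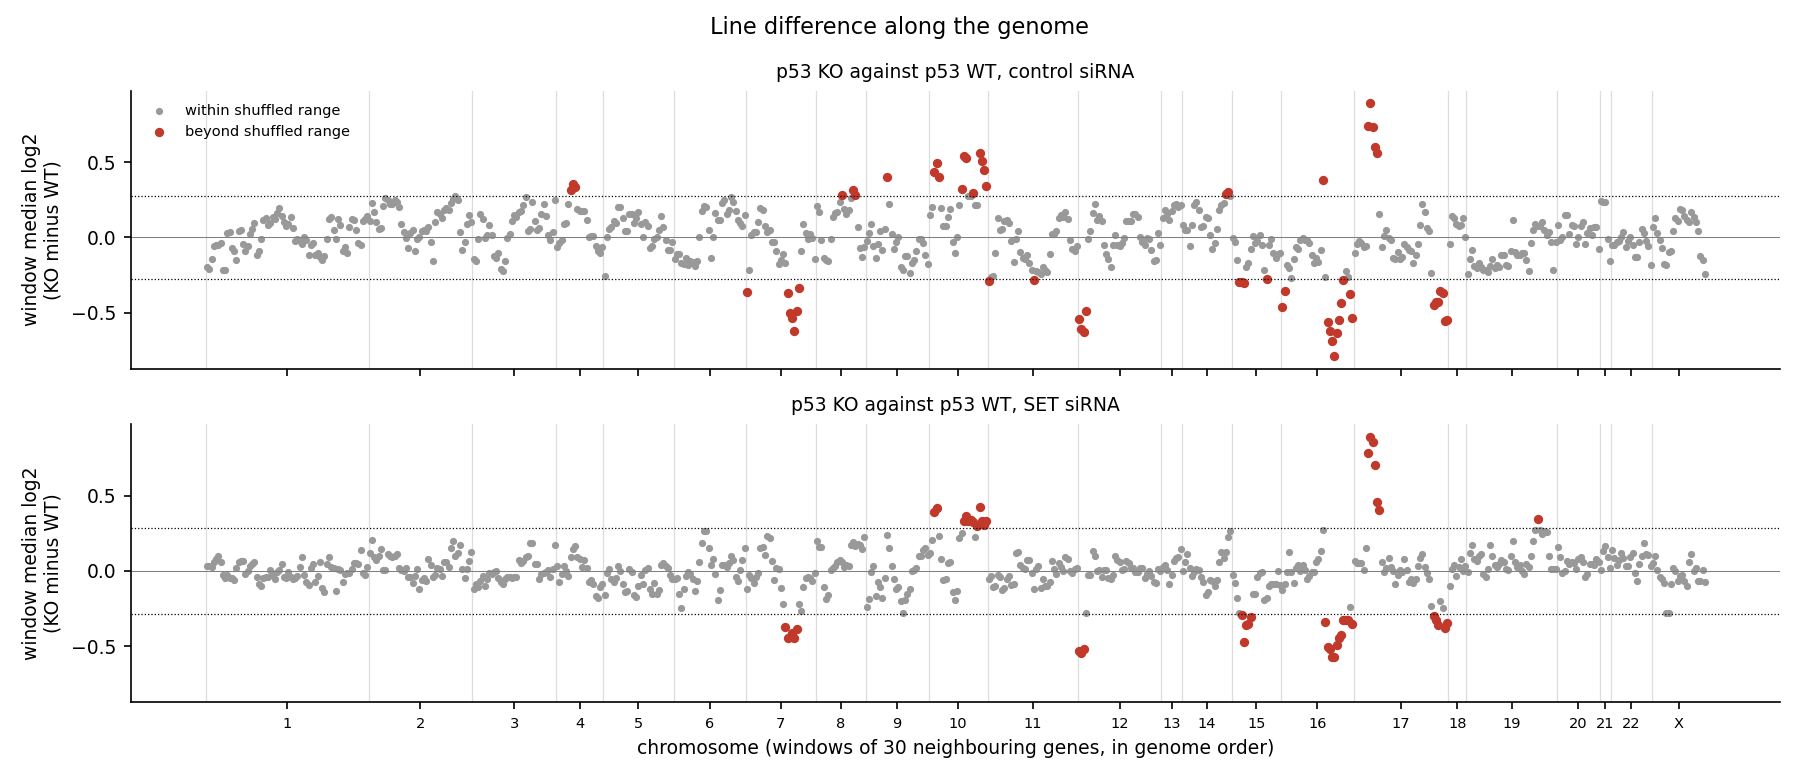
Median log2 difference between KO-labelled and WT-labelled cells in windows of 30 neighbouring genes along the chromosomes under control siRNA (top) and SET siRNA (bottom), with windows beyond the shuffled range (dotted lines) in red. Window medians of the 2 comparisons, which share no library, correlated at 0.736 across windows, which overlap.

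The same line comparison under SET siRNA asked how the lines differ with SET siRNA. CDKN1A was 19.4 ± 0.111 FPKM in KO-labelled (n = 2) and 720.3 ± 21.2 in WT-labelled cells (n = 3), a log2 difference of -5.15 (adjusted p = 4.04e-11). PVRL4, INPP5D, TRIM22, KISS1, NBEAP1 and BTG2 were lower, by -4.17 to -3.88, and MDM2 by -3.54. PDGFRA, a growth factor receptor, was at 6.18 ± 0.0609 against 0.972 ± 0.0358 FPKM, and SERPINF1, GLUL, BCR and LOC643714 were also higher, by 1.86 to 4.68. SET differed by 0.24. RN5S4 at 2.84 and NME1-NME2, a readthrough entry, at 1.92 lost their calls without KO SET siRNA library 1 (adjusted p = 0.0978 and 0.0914). RN5S4 also lost it without KO SET siRNA library 2 (0.0612) or WT SET siRNA library 2 (0.0544) or 3 (0.0545) and in a fit on only the libraries compared (0.05), and its direction turned under voom (-0.10, adjusted p = 0.919). KRTAP20-2 at 1.90 lost its call under voom (0.0704). In limma 7173 genes were called, 3501 higher and 3672 lower, with 527 at least 2-fold (137 higher, 390 lower). After quantile normalization the majority turned, with 3807 higher and 3251 lower.

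Under SET siRNA 57 of 60 p53 targets were lower in KO-labelled cells (57 adjusted over the list alone; p = 7.85e-36, and 0.000712 with an estimated correlation), with FAS at -3.35, EDA2R at -3.02 and BBC3 at -1.85. By part these were 15 of 15, 15 of 16 and 27 of 29 (15, 15 and 27 adjusted over the list alone; camera adjusted p = 1.3e-15, 1.74e-11 and 5.21e-20). All 30 G2/M genes were higher (30 adjusted over the list alone), with AURKB at 1.59 and CENPA at 1.32 (adjusted p = 3.04e-17, and adjusted p = 0.0614 with an estimated correlation). G1/S genes were higher in 36 of 39 cases and lower in 1 (36 and 1 adjusted over the list alone), with E2F2 at 1.41 and E2F1 at 1.14 (adjusted p = 1.3e-15, and 0.0209 with an estimated correlation). Chaperones were lower in 13 of 15 cases (14 adjusted over the list alone), with HSPA5 at -0.94 and HERPUD1 at -0.68 (adjusted p = 0.000165, and adjusted p = 0.335 with an estimated correlation). NF-kB genes with CSF2 at -2.72, matrix genes and epithelial markers with KRT8 at -1.34 were lower in 10 of 17, 15 of 24 and 5 of 6 cases (10, 15 and 5 adjusted over the list alone). Their camera calls were lost, with adjusted p = 0.113, 0.261 and 0.175 with an estimated correlation. The blood marker LCP1 had a log2 difference of -1.54. SET partners (14 higher and 3 lower of 27), interferon genes (4 and 13 of 22) and cholesterol genes (10 and 2 of 23) gave the same counts adjusted over the list alone, and their calls were lost, with adjusted p = 0.0987, 0.175 and 0.175 with an estimated correlation.

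Shared responses of the lines were counted directly. Of genes higher with SET siRNA 1916 were called in both lines against 901.5 for independent lists, and of genes lower 1706 against 634.4. Opposite calls numbered 129 and 135 against 814.9 and 701.8. These siRNA comparisons share no library. Of genes higher in WT-labelled cells 1113 (24.4%) had a positive interaction, against 479.7 for independent lists. The interaction contains the WT-labelled response as a term, which raises this count by construction. Genes lower in KO-labelled cells under control siRNA and higher with SET siRNA in WT-labelled cells numbered 1017 against 1014 for independent lists, and 261 of these also had a positive interaction, against 247.3, among them 44 of the 60 p53 targets. Genes lower in KO-labelled cells with a positive interaction numbered 306 against 345.9. The interaction contains the KO minus WT difference under control siRNA as a term, so the shared controls lower both counts by construction. The corresponding overlap with rises in KO-labelled cells was 999 against 650.1, or 647 with array weights and 493 in a fit on only the libraries compared. Both overlaps use shared control libraries, so part of the excess in KO-labelled cells may come from sharing. Controls were therefore split, after seeing the data, so that none served both comparisons, with a lone library assumed to vary like the other groups. The overlap in KO-labelled cells was then 752 or 681 against 480 or 549.2 for independent lists. In WT-labelled cells it was 612 to 785 over 6 splits, or 1.06 to 1.23 times that of independent lists. Across genes, which are not independent replicates, the correlation with the line difference without splitting was 0.098 for the WT-labelled response (simulated 0.453; covariance 0.0208 against 0.0242) and -0.323 for the KO-labelled response (simulated -0.543; covariance -0.0623 against -0.0347). After splitting it was -0.061 to 0.028 and -0.133 to -0.125.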

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

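All tests here were planned. Each value was singled out because the response to SET siRNA differed between the WT-labelled and KO-labelled lines by the interaction test, with positive values where the WT-labelled response was the higher. The interaction called 2831 genes. Of 20 lists tested 10 passed, with medians of 0.93 for arrest, 0.67 for apoptosis and 0.77 for repair and other p53 targets, 0.75 for their union, -0.49 for G2/M, -0.70 for G1/S, 0.37 for ATF4, 0.39 for chaperones, -0.26 for cholesterol and -0.21 for histones. The chaperone and histone calls were lost with an estimated correlation (adjusted p = 0.519 and 0.421).

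Of 82 genes named in either siRNA comparison 45 were called, 25 positive and 20 negative. Among all tested genes 19.1% were called. The named genes were chosen mostly for large siRNA changes in these libraries, so a higher share among them follows in part from the choice. Positive p53 targets were MDM2 at 2.10, GDF15 at 1.79, FAS at 1.74, INPP5D at 1.65, ACER2 at 1.57, CDKN1A at 0.74, BBC3 at 0.70, SESN2 at 0.69, APAF1 at 0.65, TNFRSF10B at 0.64 and RAP2B at 0.37. Other positive genes were NBEAP1 at 2.08, LOC100653010 at 1.63, MMP3 at 1.22, COL3A1 at 1.00, ATF3 at 0.97, CSF2 at 0.82, CHAC1 at 0.77, EDN2 at 0.73, DNAJC3 at 0.70, NOS3 at 0.67, NUPR1 at 0.48, KAT2B at 0.47, HERPUD1 at 0.39 and DDIT3 at 0.38. The scale matters for low genes. COL3A1 fell to nearly the same FPKM fraction in both lines, 0.0991 and 0.106, and CSF2 rose from 0.0996 ± 0.141 FPKM in KO-labelled cells, so neither interaction reflects the fold ratio.

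Negative cell cycle genes were CDC20 at -1.04, E2F2 at -1.04, PLK1 at -1.01, CCNE1 at -0.72, CCNE2 at -0.66, CCNA2 at -0.54, GINS1 at -0.49 and UBE2C at -0.49. The remaining negative genes were KRTAP21-2 at -3.00, HIST1H4I at -1.99, MFAP5 at -1.03, UCA1 at -0.93, TNNT2 at -0.90, LBH at -0.67, MVK at -0.63, CXCL3 at -0.60, NR4A1 at -0.54, IFIT1 at -0.49, FOSL1 at -0.37 and TGFBI at -0.36.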

How the results depend on the processing

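The other settings and the rule for named genes were set before the data were examined. The voom fit on implied fragments and the split of shared controls were chosen after seeing the data, and the planned count-based test was not run because the files hold FPKM. Of 4077 alternative values for the 208 gene values reported 4010 kept direction and side of the threshold, 65 fell below it, 1 passed it and 1 reversed. The reversal was RN5S4 between lines under SET siRNA, -0.10 under voom against 2.84, and the cause was not tested. A 2-fold minimum, stricter by construction, left 345, 247, 92, 373 and 527 genes for SET siRNA in WT-labelled cells, in KO-labelled cells, the interaction, and the lines under control and SET siRNA. A fit on only the libraries compared raised the counts for WT-labelled cells, 8117 to 8380, and the lines under SET siRNA, 7173 to 7709. It lowered those that use the KO control pair, 5571 to 3202 for KO-labelled cells and 7101 to 5353 for the lines under control siRNA. Array weights moved them the same ways, to 8962, 8388, 4320 and 5184. Fewer libraries alone do not give this split. The spread shared by all groups may be too small for the KO control pair and its calls too many, which was not tested. With each library left out in turn the counts ranged from 6989 to 8680, 3463 to 5832, 1143 to 4589, 4800 to 7554 and 5175 to 7699. The lowest for the KO-labelled comparison and for the interaction came without KO SET siRNA library 1, and the highest interaction count without KO control library 1. Leaving out a KO library leaves its group with 1, assumed to vary like the other groups. The overlap of genes lower in KO-labelled cells and higher with SET siRNA there was 647 with array weights. It was 493 in the fit on only the libraries compared, and the cause of neither value was tested. The overlap with rises in WT-labelled cells, 1017, was 612 with WT control library 2 alone and 660 with libraries 2 and 3 in the line comparison and the rest in the siRNA comparison, where each comparison has fewer controls. Median log2 change of the 60 p53 targets lay within 0.82 to 0.88, -0.05 to 0.00, 0.73 to 0.78, -1.08 to -0.92 and -1.75 to -1.69 with each library left out, and within 0.74 to 0.90, -0.05 to -0.02, 0.71 to 0.81, -1.19 to -0.94 and -1.85 to -1.62 in the other settings. A replicate block gave 8472, 6027, 3400, 7189 and 7233 calls. Deviations of same-numbered libraries correlated across genes at -0.083 to 0.228, and those of differently numbered libraries at -0.228 to 0.151. In a group of 2 libraries the deviations mirror each other. Each correlation with a KO-labelled library therefore recurs with opposite sign for the other, and the 2 ranges are not separate evidence. The highest correlations, 0.217 and 0.228, joined same-numbered control siRNA libraries of the lines, so a pairing of those libraries stays open. Depth limits low genes most, since authors' intervals had a median half-width per library of 17.75 to 22.09% for genes at FPKM 1 to 5 and 3.43 to 4.19% at FPKM of at least 50.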

Other observations

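The tests of a WT-cell share, with their bounds, and of reads shared with SETP20 were chosen only after the results were seen. Ferroptosis and iron genes rose in 6 of 10 cases and fell in 2 with SET siRNA in WT-labelled cells (6 and 2 adjusted over the list alone; camera adjusted p = 0.148), with HMOX1, heme oxygenase, at 0.77 and the ferritin chain FTH1 at 0.57. Immediate early genes rose in 7 of 12 cases and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0927), with IER3 at 0.90 and FOSL1 at 0.63. In KO-labelled cells they rose in 8 and fell in 3 (8 and 3 adjusted over the list alone), with NR4A1 at 1.18 and IER3 at 1.08 (adjusted p = 0.0251, and adjusted p = 0.435 with an estimated correlation). Hypoxia and glycolysis genes had 5 rises and 4 falls among 23 in WT-labelled cells (4 and 2 adjusted over the list alone; adjusted p = 0.826), with SLC2A1 at -0.67 and ALDOC at 0.62. Their median of 0.03 and mean of 0.02 stood against a camera direction of down, and the median was -0.01 after median-of-ratios scaling.

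Cytosolic ribosomal protein genes rose in 32 of 78 cases and fell in 1 with SET siRNA in WT-labelled cells (30 and 1 adjusted over the list alone), with RPL13A at 0.40 and RPS29 at -0.75 (adjusted p = 0.00522, and adjusted p = 0.45 with an estimated correlation). After median-of-ratios scaling 22 rose. In KO-labelled cells 19 rose (1 adjusted over the list alone), against 10 after that scaling and 11 after quantile normalization. Histone genes fell in 13 of 35 cases and rose in 5 in WT-labelled cells (13 and 5 adjusted over the list alone), with HIST1H4I at -1.44 and HIST1H2AG at -1.25 (adjusted p = 0.0388, and adjusted p = 0.399 with an estimated correlation). HIST1H2AC had an interaction of -1.01 (adjusted p = 0.0185), lost without KO control library 2 (0.0693) or KO SET siRNA library 1 (0.0808). Of markers of other cell types, epithelial ones had 2 rises and 3 falls among 6 in WT-labelled cells (2 and 3 adjusted over the list alone; adjusted p = 0.425), with EPCAM at 0.84 and KRT8 at -0.54. Blood markers had LAPTM5 at 0.39 and CORO1A at -0.23 (adjusted p = 0.0453) called. CORO1A lost its call without WT control library 1 (0.139) or 2 (0.0917), WT SET siRNA library 1 (0.132) or 2 (0.12), or KO SET siRNA library 1 (0.0508) or 2 (0.0505), with no filter (0.0713) and under voom (0.0814). The endothelial markers EGFL7 at 0.08 (adjusted p = 0.517) and ERG at -0.37 were too few for a list test.

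In KO-labelled cells 14 of the 60 p53 targets, CDKN1A among them, rose with SET siRNA and 14 fell. Of all 14813 tested genes 2926 were called higher there, a similar share, and the joint p53 list was not called. The rises therefore do not set the targets apart as a list. All 14 targets that rose kept their call after median-of-ratios scaling, which argues against a scaling shift of those libraries. A share of WT-labelled cells above 2.687% would bring more CDKN1A than was measured. With 2 standard errors taken off each FPKM rise, an equal share of that size under both siRNAs would supply a median of 17.48% of the rise of the other 13 targets and at most 55.91% for any, which argues against it as their whole cause. A share in the SET siRNA cultures alone would supply a median of 30.88% and under 100% for 12 of them, which argues against it likewise, while for BAX, with its wide spread, it reached 128.15% and stays open. For CDKN1A an equal share set by the 5 genes lowest in KO-labelled cells supplied 100.4% of the rise and one set by the lowest 26.3%, which leaves a mixed culture open, and a p53-independent response is an untested hypothesis beside it.

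The regional differences between the lines may be differences in genomic copies, which is a hypothesis. Window medians of the 2 line comparisons, which share no library, correlated at 0.736 across overlapping windows. Any stable regional difference between the same 2 lines would give such a correlation, so it does not single out genomic copies. Other regional causes were not tested. Without p53 targets and interaction genes 97.4% of shared windows stayed beyond the shuffled range with control siRNA, which argues against the listed targets as their source. Only 6 of the 60 listed targets lay among the 750 genes of these windows, so this outcome was nearly fixed in advance. Genes that depend on p53 but are outside the lists were not tested.

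SETP20 fell with SET in both lines, and reads shared with its near-identical parent may be the source. The SETP20 level was 1.95 to 4.63% of that of SET, and the highest over the lowest was 2.38, which leaves this open. For SET siRNA in WT-labelled cells the 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 8117 genes, 1 split of the 10 reached that, and the highest other called 3.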
